A study of Mus musculus with 12 samples.

How the data were processed

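RNA from flushed oviducts and flushed uterine horns of mice in preimplantation pregnancy was measured on 12 Affymetrix mouse gene arrays, with a single biotin-labelled sample on each. Per the labels' protocols, mice were injected under the skin each day from day 0.5 to day 2.5 with estradiol (E2) at 10 µg/kg or with the sesame oil vehicle alone (0 µg/kg, 100 µl), and tissue was taken on day 3.5 and frozen before TRIzol extraction. The labels give 4 groups of 3 biological replicates, which are oil uterus, E2 uterus, oil oviduct and E2 oviduct. Other E2 doses of the study were not analysed here. The deposited table holds an intensity for each probe set and array, which the authors made with RMA per the labels. The RMA version and any further step are not given in the sources used here. The values proved to be linear and not log2 as assumed when the tests were chosen, since none was 0 or below and the array maxima lay between 9102 and 9950. They were therefore log2 transformed before any test. Scan dates, scanner files and detection calls were not used here.

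The table had 35556 probe sets. A gene table built from the platform annotation listed 23410 of them, 21789 with a single symbol and 1621 with several, and 12146 had no listed gene. Gene identifiers of 21698 single-symbol probe sets matched the mouse gene table of assembly GRCm38.p6, which was used for names and for neighbouring genes. A gene was represented by its probe set with the highest mean over the 12 arrays among single-symbol probe sets, which gave 19938 genes, 999 of them with more than 1 probe set. Probe sets of a gene called in opposite directions occurred for 1 gene in the uterus and 0 genes in the oviduct. No intensity filter was applied. Y-linked genes, which female tissue lacks, gave a background level, and their highest log2 value on any array was 7.50 (Sry), or 4.40 without Sry. On all 12 arrays, 10257 genes lay below 7.50, so small changes among them have a limited signal. That bound rests on Sry alone and lies above the highest array median (log2 6.54), so a gene below it need not be undetected. Where a group mean of a gene lay below 7.50, the exact size of its fold change is uncertain. The number of arrays limits the precision, and exact tests of 3 against 3 arrays cannot give a p below 0.10.

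All 12 arrays were fitted together as 4 group means with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Log2 fold changes are given with the standard error (SE) of that fit. Comparisons were E2 against oil in each tissue, the difference between those effects (the interaction contrast), and oviduct against uterus in oil mice. In total 38 gene lists (pathways and cell type markers) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated for each list and with fry. Of 564 listed genes 520 were measured, and 44 were not analysed here. Tests, lists, alternatives and the rule for named genes were chosen before the data were examined. That rule took up to 10 genes of each direction by absolute log2 fold change past the test with no overlap between the arrays of the E2 and oil groups, up to 6 of each sign for the interaction, and up to 5 for the tissue comparison. It added up to 4 members of each list past the test (or 2 as values where none passed). Genes past the test in both tissues were added too, up to 6 in the same direction and 6 in opposite directions. Esr1, Esr2, Pgr, Ltf, Ovgp1, Foxj1, Lif and Ihh were always included where measured, and no value of Ovgp1 is given here. Calls that a single left-out array ended were passed over where other members could be named, a step added after the values were seen.

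The fit was tested on simulated arrays with 200 genes changed by known amounts. At a log2 change of 1, it recovered 91.0% of changed genes in the simulated uterine comparison and 97.0% in the oviductal one. At a log2 change of 0.5, the shares were 62.7% and 56.7%. Unchanged genes called were 6 and 2. The simulated noise was independent between genes, no array was displaced as a whole, and only 200 of 19938 genes changed. In the real uterus 26.7% of genes were called, so these shares and error counts need not hold for the data. The alternatives were a fit for each tissue alone, replicate blocks, intensity filters, other gene measures, other scalings, another variance model, array weights, a fold threshold and leaving out each array in turn. Leaving out both arrays of oil replicate 3 was added after seeing the data.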

Results

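Expression of 19938 genes was measured in uterus and oviduct at the end of preimplantation development, to ask how excess E2 changes the tissue that receives the embryo and the tissue that transports it. Each group of oil or E2 mice had 3 arrays. Array median intensities lay between 89.5 and 92.9. Arrays of a group correlated across genes at Pearson r 0.984 to 0.996, over genes that are not independent replicates. The first principal component (65.3% of the variance) separated the tissues and the second (18.1%) separated E2 from oil uterus.

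**Figure D1:**
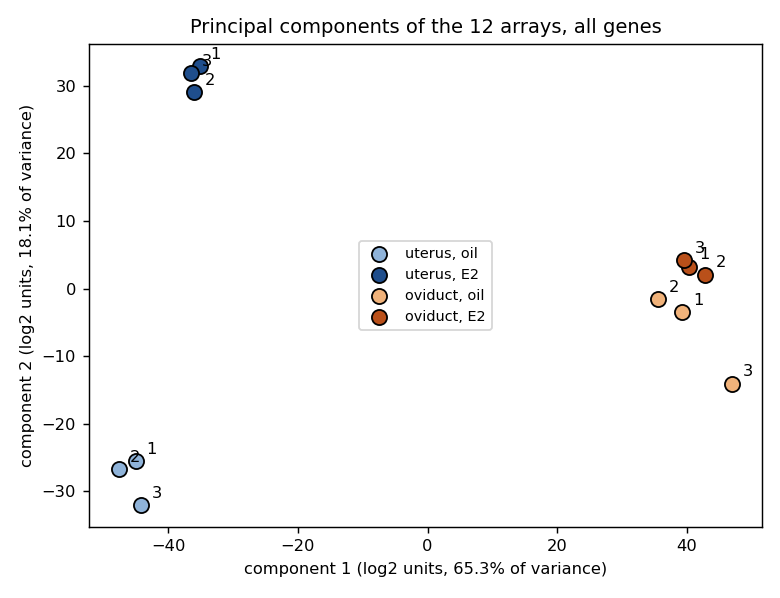
Principal components 1 and 2 (log2 units) of the 12 arrays, each point an array with its replicate number. Component 1 holds 65.3% and component 2 18.1% of the variance, and the E2 and oil arrays lie farther apart in uterus than in oviduct.

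Oil replicate 3 stood apart in both tissues. In it, 177 uterine and 302 oviductal genes lay more than 1 log2 unit from the mean of the other 2 oil arrays of that tissue, against 8 to 62 genes in each of the other 10 arrays. Both sets shared 60 genes (2.68 expected of independent sets), of which 52 moved the same way. Trim30d, an antiviral TRIM family gene, lay -3.89 log2 units from the other arrays in uterus and -3.63 in oviduct. The antigen-presenting gene H2-Eb1 lay -2.85 and -3.14 away, and the interferon-inducible Ifi202b 3.64 and 2.62. The oviduct array of oil replicate 3 also held genes of the corpus luteum, with the progesterone-inactivating Akr1c18 displaced by 6.88 and the steroid-making Cyp11a1 by 4.44 and Star by 2.94. These genes were chosen after their values were seen. The labels do not say whether equal numbers stand for the same mouse.

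**Figure D2:**
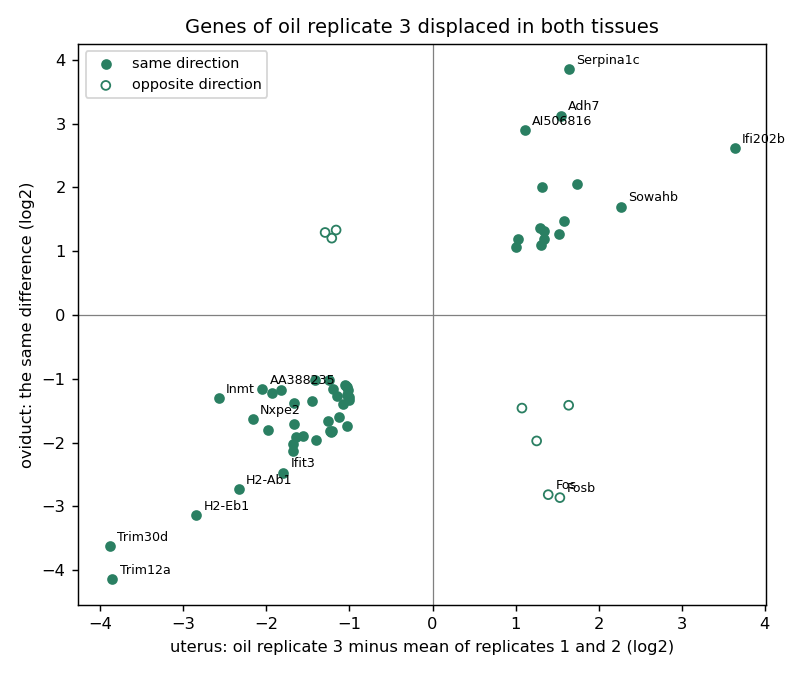
Log2 difference of oil replicate 3 from the mean of oil replicates 1 and 2 in uterus (horizontal) and oviduct (vertical), for the 60 genes over 1 log2 unit away in both tissues. Filled points mark the 52 genes that moved the same way.

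In the uterus, E2 raised 7 of 9 oviduct secretory markers and 12 of 20 mucosal defence genes and lowered 14 of 20 progesterone-dependent and 24 of 27 cell cycle genes. With estimated correlations camera called 0 of the 38 lists in this comparison. By limma, 2478 genes rose and 2854 fell (26.7% of those tested), 405 and 281 of them by at least 2-fold (n = 3 arrays per group). Ltf, the iron-binding antimicrobial lactoferrin and a classic E2 target, rose by 5.45 log2 units (SE 0.19, adjusted p = 2.7e-08). Lcn2, which binds bacterial siderophores, rose by 5.14 (SE 0.21), and the mucin Muc4 by 3.99 (SE 0.22). Lrp2, an endocytic receptor dependent on progesterone, fell by 4.30 (SE 0.23) to a mean of 5.76, below the highest Y-linked value of 7.50, so the exact size of its fall is uncertain.

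Other large rises were those of Clca1, a secreted regulator of chloride currents (6.78, SE 0.70), the diamine oxidase Aoc1 (5.61, SE 0.16), the proline-rich acidic protein Prap1 (5.45, SE 0.32), the GABA receptor subunit Gabrp (5.28, SE 0.18) and the gap junction protein Gjb2 (4.12, SE 0.21). Complement factor Cfb rose by 3.93 (SE 0.20). Large falls included the trypsin inhibitor Spink1 (-3.92, SE 0.24), the itaconate-making enzyme Acod1 (-3.85, SE 0.28), the sialic acid lyase Npl (-3.70, SE 0.21), Angptl7 (-3.32, SE 0.14) and Ndp, a ligand of the Wnt receptor Fzd4 (-2.68, SE 0.12). Ddah1, which degrades an inhibitor of nitric oxide synthesis, fell by 2.75 (SE 0.08). Tmem45b rose by 3.82 (SE 0.50), and by 3.30 without oil replicate 3, in which it was 1.55 log2 units lower. Oil uterus means of Clca1 (5.58), Aoc1 (5.67), Prap1 (5.77), Gabrp (5.44), Ltf (6.60), Lcn2 (7.39), Gjb2 (5.60), Muc4 (5.99) and Cfb (7.18) lay below the highest Y-linked value of 7.50, so their exact folds and interaction differences are uncertain. The same holds for falls that ended below it in E2 uterus, of Spink1 (3.51), Acod1 (5.77), Npl (6.66), Angptl7 (7.01), Ndp (6.60) and Ddah1 (6.15).

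Known E2-induced genes rose in 14 of 22 measured members and fell in 3 (median 1.21; adjusted over the list alone, 14 and 4). They included Clca1, Ltf, Lcn2 and the matrix protease Mmp7 (3.65, SE 0.34), whose oil uterus mean of 5.97 also lay below 7.50. In oil uterus replicate 3, 15 of the 22 genes lay higher than in the other oil arrays (median displacement 0.22; list median on that array -0.067 against -0.70 and -0.84), and without oil replicate 3 the median was 1.40 with 14 genes higher and 3 lower. The camera adjusted p was 1.1e-06, and the adjusted p was 0.0997 with an estimated correlation. Progesterone-dependent genes fell in 14 of 20 members and rose in 0 by limma (median -0.88; adjusted over the list alone, 16 fell), with 0 of 20 risen adjusted over the list alone as well. Examples besides Lrp2 and Acod1 were the interleukin 13 decoy receptor Il13ra2 (-2.43, SE 0.30) and the activin inhibitor Fst (-2.10, SE 0.10). Ihh, the epithelial hedgehog signal of the receptive uterus, fell by 0.84 (SE 0.19). The camera adjusted p was 8.1e-12, and the adjusted p was 0.0518 with an estimated correlation. Endometrial gland genes fell in 5 of 11 members and rose in 1 (median -0.74; adjusted over the list alone, 6 and 1), led by Spink1, the chemokine Cxcl15 (-2.76, SE 0.35) and the calcium-binding Calb1 (-1.70, SE 0.27). For these genes the camera adjusted p was 0.0032, and the adjusted p was 0.25 with an estimated correlation. In oil uterus replicate 3 the gland list lay at a median of 1.00 log2 units above the other oil arrays, and without oil replicate 3 the list's median was -0.32 with 5 genes lower. The member that rose, Sprr2f, belongs to a family with near-identical copies and is uncertain.

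Cell cycle genes fell in 24 of 27 members and rose in 0 by limma (median -1.17; adjusted over the list alone, 26 fell and 0 rose). The mitotic checkpoint kinase Bub1 (-1.87, SE 0.40), the DNA topoisomerase Top2a (-1.75, SE 0.30), cyclin A2 (Ccna2; -1.68, SE 0.32) and the mitotic kinase Cdk1 (-1.57, SE 0.40) were among them. The camera adjusted p was 1.1e-14, and the adjusted p was 0.25 with an estimated correlation. In oil uterus replicate 3, 25 of the 27 genes lay below the other oil arrays (median displacement -0.74), and without oil replicate 3 all 27 fell. Protein folding and endoplasmic reticulum stress genes fell in 9 of 16 members and rose in 1 (median -0.54; adjusted over the list alone, 11 and 1), with the asparagine synthetase Asns at -1.09 (SE 0.10) and the chaperone Hspa5 at -0.82 (SE 0.16). Camera gave them an adjusted p of 0.00076, and the adjusted p was 0.53 with an estimated correlation. Sterol synthesis genes fell in 10 of 14 members and rose in 1 (median -0.42; adjusted over the list alone, 10 and 1). Idi1 fell by 1.73 (SE 0.16), with a camera adjusted p of 0.0051 and an adjusted p = 0.57 with an estimated correlation. All 16 folding genes and 13 of 14 sterol genes lay higher in oil uterus replicate 3 than in the other oil arrays, by medians of 0.22 and 0.20.

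Epithelial markers rose in 13 of 14 members (median 0.90; adjusted over the list alone, 13 rose and 1 fell), among them the transcription factor Elf3 (2.58, SE 0.15) and the keratins Krt7 (2.13, SE 0.16) and Krt19 (1.93, SE 0.12). The camera adjusted p was 1.4e-11, and the adjusted p was 0.10 with an estimated correlation. This rise of epithelial markers accompanied each of the following epithelial groups. Some lists share members, with Krt7 in the epithelial and oviduct secretory lists and Lcn2 and Wfdc2 in the oviduct secretory and mucosal defence lists. Markers of oviduct secretory cells rose in 7 of 9 members and fell in 0 by limma (median 1.18; adjusted over the list alone, 7 and 1), including the antioxidant enzyme Gpx3 (1.30, SE 0.11) and the anion exchanger Slc26a4 (1.18, SE 0.07). By camera the adjusted p was 8.3e-06, and the adjusted p was 0.0518 with an estimated correlation. Mucosal defence genes rose in 12 of 20 members and fell in 1 (median 0.74; adjusted over the list alone, 12 and 2). Besides Ltf, Lcn2 and Muc4, the antibody transporter Pigr rose by 3.48 (SE 0.20), from an oil mean of 6.74. For these genes the camera adjusted p was 4.7e-08, and the adjusted p was 0.0534 with an estimated correlation. Ion and water transport genes rose in 11 of 26 members and fell in 3 (median 0.13; adjusted over the list alone, 11 and 4), led by Clca1, the calcium channel Trpv6 (3.60, SE 0.20) and the chloride channel Cftr (2.66, SE 0.13), from oil means of 5.90 for Trpv6 and 5.02 for Cftr, while the calcium-binding S100g fell by 1.59 (SE 0.19). Camera gave them an adjusted p of 0.0085, and the adjusted p was 0.23 with an estimated correlation. Cornified envelope genes rose in 5 of 15 members and fell in 0 by limma (median 0.07; adjusted over the list alone, 5 rose), with Sprr2b at 3.60 (SE 0.16) and Sprr2d at 1.85 (SE 0.21) in a family of near-identical copies. By camera the adjusted p was 0.043, the call ended when E2 uterus replicate 1 (median 0.046) or oil uterus replicate 2 (0.030) or oil oviduct replicate 3 (0.069) was left out, and the adjusted p was 0.71 with an estimated correlation.

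Of immune lists, camera called those of complement, macrophages and interferon, while cytokine and chemokine genes went both ways (6 of 25 higher and 4 lower; adjusted over the list alone, 7 and 6). Lists of neutrophil, T cell and B cell markers were not called. Complement genes rose in 9 of 15 members and fell in 0 by limma (median 0.69; adjusted over the list alone, 11 rose), led by Cfb and by the inhibitor Cfi (3.77, SE 0.40). Cfi was 1.13 log2 units lower in oil uterus replicate 3, and its rise was 3.40 without oil replicate 3. For these genes the camera adjusted p was 6.0e-06, and the adjusted p was 0.0997 with an estimated correlation. Macrophage markers, which share the C1q genes with complement, rose in 7 of 10 members and fell in 0 by limma (median 0.72; adjusted over the list alone, 8 rose). The lysosomal Cd68 rose by 1.22 (SE 0.16) and the growth factor receptor Csf1r by 1.12 (SE 0.14). In oil uterus replicate 3, 8 of the 10 markers lay lower (median displacement -0.20), and without oil replicate 3 the median was 0.63 with 8 genes higher. Camera gave them an adjusted p of 5.2e-05, and the adjusted p was 0.48 with an estimated correlation. Interferon-stimulated genes rose in 11 of 17 members and fell in 0 by limma (median 0.78; adjusted over the list alone, 12 rose), with Mx1 at 1.76 (SE 0.20) and Irf7 at 1.34 (SE 0.33). By camera the adjusted p was 2.0e-05, and the adjusted p was 0.53 with an estimated correlation. All 17 interferon genes lay lower in oil uterus replicate 3 (median displacement -0.61), and without oil replicate 3 the median was 0.53 with 11 genes higher.

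Smooth muscle genes rose in 4 of 16 members and fell in 0 by limma (median 0.32; adjusted over the list alone, 5 rose), with Tagln at 0.59 (SE 0.14). For these genes the camera adjusted p was 0.0038, and the adjusted p was 0.71 with an estimated correlation. In oil uterus replicate 3, 15 of the 16 genes lay higher (median displacement 0.48), and without oil replicate 3 11 genes rose. Endothelial markers fell in 9 of 12 members and rose in 2 (median -0.39; adjusted over the list alone, 9 and 2), with the junction proteins Cdh5 at -0.95 (SE 0.11) and Esam at -0.78 (SE 0.09). Camera gave them an adjusted p of 0.0011, and the adjusted p was 0.53 with an estimated correlation. Among lists that camera did not call, signals acting on muscle tone went both ways, with 10 of 29 genes higher and 9 lower (adjusted over the list alone, 11 and 10). The oxytocin receptor Oxtr rose by 1.10 (SE 0.12) and the prostaglandin F receptor Ptgfr fell by 1.13 (SE 0.15). Receptivity genes rose in 6 of 17 members and fell in 3 (adjusted over the list alone, 6 and 5), among them the LIF receptor Lifr (1.71, SE 0.10) and the prostaglandin synthase Ptgs2 (1.08, SE 0.21). Matrix genes rose in 6 of 22 members and fell in 7 (adjusted over the list alone, 7 and 8), with the protease Mmp11 at 2.15 (SE 0.09) and the hyaluronan synthase Has2 at -2.56 (SE 0.13). Stromal markers fell in 4 of 12 members and rose in 1 (adjusted over the list alone, 5 and 1), and ciliated cell genes fell in 2 of 29 and rose in 1 (2 and 0 over the list alone). Of 8 steroid receptor genes 0 passed limma's test, with Esr1 at 0.10 (SE 0.06), Esr2 at 0.04 (SE 0.08) and Pgr at -0.40 (SE 0.15). At an unadjusted p under 0.05 there were 2. Without oil replicate 3, Pgr passed it at -0.32. Lif, a gland signal for implantation, was at -0.67 (SE 0.24, adjusted p = 0.0568), and at -0.32 without oil replicate 3, in which it lay 1.06 higher, and Foxj1 at 0.11 (SE 0.26).

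In 40.5% of genes the uterine E2 and oil arrays did not overlap, where chance gives 10%, and 7193 genes had an unadjusted p under 0.05. Camera called 10 lists higher and 6 lower of 38. With estimated correlations it called 0, and fry called 17. Without both oil replicate 3 arrays, 2694 genes rose and 2898 fell.

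In the oviduct, far fewer genes passed the test. By limma, 32 genes rose and 26 fell (0.29% of those tested), 14 and 10 of them by at least 2-fold (n = 3 arrays per group). Scgb1c1, a secretoglobin, rose by 2.37 log2 units (SE 0.17, adjusted p = 0.00032) and the membrane dipeptidase Dpep1 by 1.73 (SE 0.14). The sodium-coupled inositol transporter Slc5a11 fell by 2.05 (SE 0.24) and Ano2, a calcium-activated chloride channel, by 1.95 (SE 0.22). All 4 kept their calls when any single array was left out, which was also a reason to name them. Of 27 oviductal calls under the rule for named genes, 11 kept theirs in this way, and 10 did in a fit of the oviduct arrays alone. E2 oviduct means of Slc5a11 (5.85) and Ano2 (5.39) and the oil mean of Scgb1c1 (6.57) lay below the highest Y-linked value, so their exact folds are uncertain.

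The focal adhesion protein Tns4 rose by 1.29 (SE 0.14) and the matrix protein Chad by 1.21 (SE 0.11). Klk1b1 rose by 1.68 (SE 0.14), and this kallikrein has near-identical copies, so its identity is uncertain. Falls included the acyl-CoA-binding Acbd7 (-1.57, SE 0.16), the sialyltransferase St6gal2 (-1.47, SE 0.18), the calcium release channel Itpr2 (-1.12, SE 0.09) and the lysosomal protease Ctsd (-1.08, SE 0.10). These 7 genes also kept their calls with any single array left out, while Ano2 and St6gal2 lost theirs in a fit of the oviduct arrays alone. Means of Klk1b1, Acbd7 and St6gal2 lay below the highest Y-linked value in both oviduct groups, and that of Tns4 in oil oviduct (6.50), so these folds are uncertain too. Dcpp2, of a secreted family with near-identical copies, rose by 2.59 (SE 0.34), and by 2.15 without oil replicate 3. Its call ended without E2 oviduct replicate 2 (2.47) or 3 (2.43). Wfdc2, a secreted protease inhibitor, fell by 0.95 (SE 0.12), and its call ended without E2 oviduct replicate 1 (-0.91) or 2 (-0.95). In the fit of the oviduct arrays alone the calls of Dcpp2, Wfdc2 and Npl ended too. Npl fell by 1.56 (SE 0.21), with the call ended without oil oviduct replicate 1 (-1.51) or E2 oviduct replicate 1 (-1.59), 2 (-1.58) or 3 (-1.51).

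Of E2-induced genes 0 of 22 passed limma's test in oviduct, and 5 had an unadjusted p under 0.05 (adjusted over the list alone, 3 rose and 1 fell). Ltf, already abundant in oil oviduct at a mean log2 intensity of 10.73, was at 0.22 (SE 0.19, adjusted p = 0.75), and Lcn2 at 0.97 (SE 0.21). Both were higher in oil oviduct replicate 3 than in the other oil arrays, by 0.81 and 0.66, and passed the test without oil replicate 3, at 0.49 and 1.19. Steroid receptors stayed within the test's threshold in all 8 measured genes, with Esr1 at 0.05 (SE 0.06), Esr2 at 0.02 (SE 0.08) and Pgr at -0.33 (SE 0.15). Only 1 of the 8 had an unadjusted p under 0.05. Ihh was at -0.23 (SE 0.19), Lif at -0.17 (SE 0.24) and the ciliated cell regulator Foxj1 at -0.14 (SE 0.26), or 0.24 without oil replicate 3. Of cell cycle genes 0 of 27 passed limma's test, with 1 at an unadjusted p under 0.05 (median 0.03). The list was called higher by camera, at a median of 0.13, without both oil replicate 3 arrays. Of signals acting on muscle tone 0 of 29 passed it, with 5 at an unadjusted p under 0.05. Without oil replicate 3, the prostaglandin receptor Ptger2 (-0.69) and the receptor activity modifier Ramp3 (-0.90) passed it.

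Macrophage markers were shifted higher in oviduct (median 0.51, camera adjusted p = 1.4e-07, adjusted p = 0.88 with an estimated correlation). By limma 0 of 10 passed the test over all genes, while 8 had an unadjusted p under 0.05 and all 8 passed it adjusted over the list alone. Adgre1 was at 0.70 (SE 0.22) and C1qc at 0.66 (SE 0.18). All 10 markers lay lower in oil oviduct replicate 3 (median displacement -0.61), and without oil replicate 3 the list's median was 0.36, still called by camera. Complement genes were shifted higher too (median 0.43, camera adjusted p = 7.4e-05, adjusted p = 0.56 with an estimated correlation). By limma 0 of 15 passed over all genes, 7 had an unadjusted p under 0.05 and 5 passed it adjusted over the list alone, and in oil oviduct replicate 3 the list lay at -0.20. Without oil replicate 3 its median was 0.22, still called. Matrix genes were at a median of 0.14 (camera adjusted p = 0.0051, adjusted p = 0.88 with an estimated correlation), with 0 of 22 past limma's test, 5 at an unadjusted p under 0.05, and 0 adjusted over the list alone. Their oil oviduct replicate 3 displacement was -0.09, and their median without oil replicate 3 was 0.083.

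Calls of handling-stress (immediate early) genes and of ciliated cell genes depended on oil replicate 3. Immediate early genes had a median of 0.56 (camera adjusted p = 0.0051, adjusted p = 0.88 with an estimated correlation), with 0 of 12 past limma's test and 0 at an unadjusted p under 0.05. All 12 lay lower in oil oviduct replicate 3 (median displacement -1.41), and without oil replicate 3 the median was 0.020 and the call ended. That call also ended without E2 oviduct replicate 1 (0.35) or 2 (0.42). Ciliated cell genes had a median of -0.18 (camera adjusted p = 0.0051, adjusted p = 0.88 with an estimated correlation), with 0 of 29 past limma's test and 1 at an unadjusted p under 0.05. All 29 lay higher in oil oviduct replicate 3 (median displacement 0.80), and without it the list turned to 0.096, called higher by camera.

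Oviductal E2 and oil arrays did not overlap in 17.4% of genes, where chance gives 10%, and 2094 genes had an unadjusted p under 0.05. Without both oil replicate 3 arrays 49 genes rose and 72 fell, and 46 of the 58 calls were shared. Leaving out any array other than those of oil replicate 3 left 7 to 20 genes higher and 7 to 15 lower, fewest without an E2 oviduct array, and a fit of the 6 oviduct arrays alone called 6 higher and 4 lower. The split of higher and lower calls was 37 and 19 after quantile scaling within tissue, and 42 and 22 with arrays centred on the median.

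**Figure D3:**
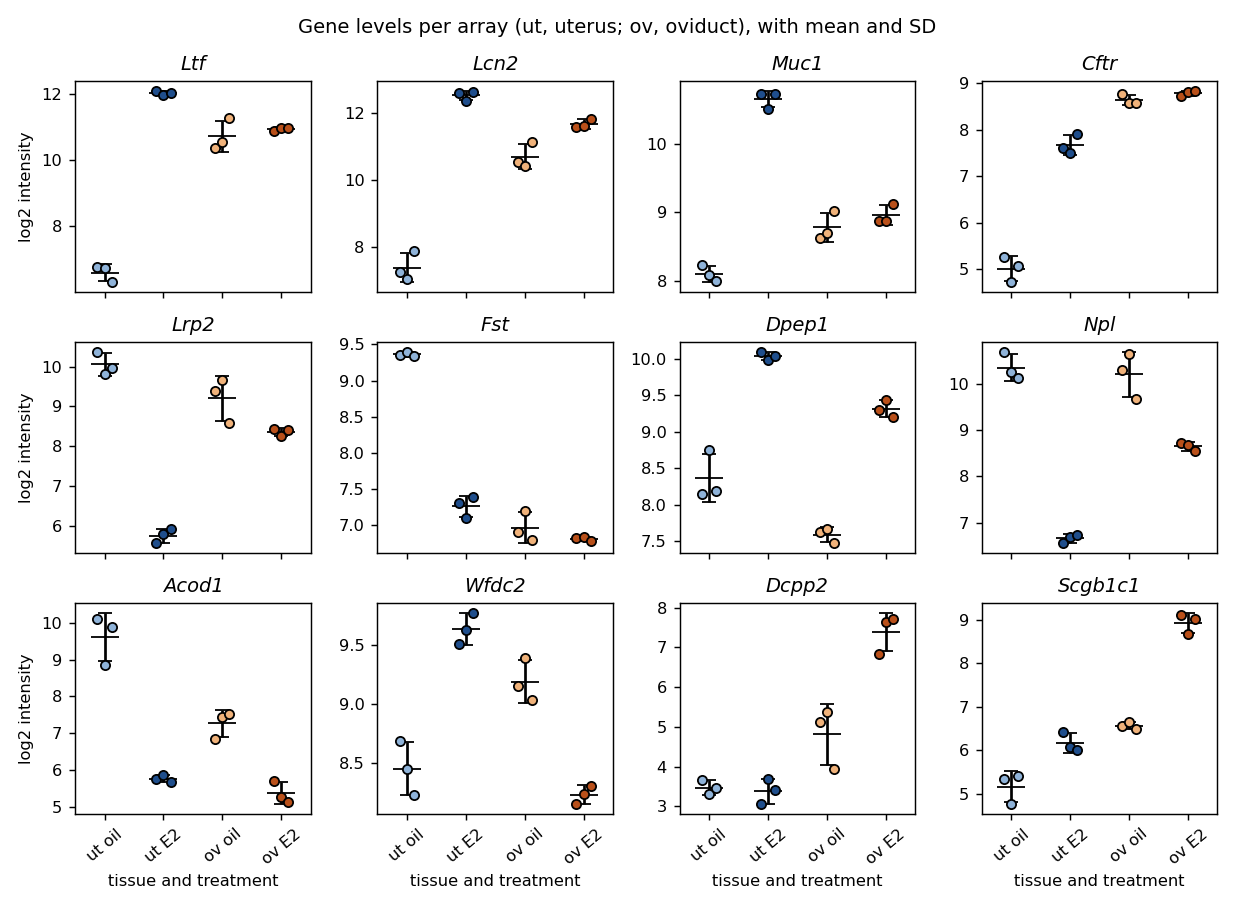
Log2 intensity per array (points) with the mean and SD of the 3 arrays of each group, for 12 named genes in uterus (blue) and oviduct (orange), each with oil and E2. Ltf is at a mean of 6.60 in oil uterus, 12.05 in E2 uterus and 10.73 in oil oviduct.

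The E2 effect differed between the tissues for 2288 genes by limma's interaction test, with 1150 more positive and 1138 more negative in oviduct than in uterus. The difference was -5.23 log2 units for Ltf (SE 0.27, adjusted p = 2.2e-06), -4.17 for Lcn2 (SE 0.30) and -6.13 for Clca1 (SE 0.99), genes that rose in uterus. It was 3.87 for Spink1 (SE 0.33), 3.46 for Lrp2 (SE 0.33) and 2.89 for Il13ra2 (SE 0.42), genes that fell in uterus. Means of Spink1 and Il13ra2 lay below the highest Y-linked value in all 4 groups (7.43 and 7.44 in oil uterus), and that of Lrp2 in E2 uterus, so the exact differences are uncertain. Aoc1 (-5.60, SE 0.23), Prap1 (-5.14, SE 0.45), Gabrp (-5.13, SE 0.25), Angptl7 (3.56, SE 0.20), Cxcl15 (3.17, SE 0.49) and Ndp (2.95, SE 0.17) differed in the same sense, each with at least 1 group mean below that value.

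Groups differed as well. Progesterone-dependent genes had a more positive effect in oviduct in 11 of 20 members and a more negative one in 0 by limma (median 0.77; adjusted over the list alone, 13), and the adjusted p was 0.040 with an estimated correlation. Oviduct secretory markers had a more negative effect in 7 of 9 (median -1.02; adjusted over the list alone, 7, and 1 more positive), with adjusted p = 0.024 with an estimated correlation. Mucosal defence genes had it in 10 of 20 (median -0.63; adjusted over the list alone, 10, and 1 more positive), with adjusted p = 0.040 with an estimated correlation. Epithelial markers were more negative in 12 of 14 (median -1.01; adjusted over the list alone, 13; camera adjusted p = 3.6e-16), and the adjusted p was 0.0576 with an estimated correlation. E2-induced genes were more negative in 13 of 22 and more positive in 1 (median -1.50; adjusted over the list alone, 13 and 2; camera adjusted p = 3.2e-08), with adjusted p = 0.0576 with an estimated correlation. Cell cycle genes were more positive in 20 of 27 (median 1.14; adjusted over the list alone, 24; camera adjusted p = 6.9e-17), with adjusted p = 0.29 with an estimated correlation. Top2a differed by 1.77 (SE 0.43) and Ccna2 by 1.78 (SE 0.45). In oil replicate 3 the cell cycle list lay at -0.74 in uterus and 0.25 in oviduct relative to the other oil arrays.

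By camera 6 lists were more positive and 9 more negative, of which 3 held with an estimated correlation, and 4717 genes had an unadjusted p under 0.05. Without both oil replicate 3 arrays, 1372 genes were more positive and 1440 more negative. The count of 1150 became 729 without E2 oviduct replicate 3 and 760 without E2 uterus replicate 1.

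Genes that passed the test in both tissues mostly moved the same way. Of the 58 oviductal calls, 13 rose in both tissues (3.98 expected of independent lists, one-sided Fisher's exact p = 5.7e-05 across genes) and 20 fell in both (3.72 expected, p = 1.2e-12). The labels do not say whether the same mice gave both tissues. If they did, differences between mice could enter both effects, which these expected counts and p-values do not allow for. Falls in uterus and oviduct were -3.85 and -1.90 for Acod1, -3.70 and -1.56 for Npl, -2.20 and -2.05 for Slc5a11, and -1.91 and -1.47 for St6gal2. Dpep1 rose by 1.68 and 1.73. The oviductal call of Acod1 ended without E2 uterus replicate 1, without oil oviduct replicate 2 (-1.81) or 3 (-1.76), or without any E2 oviduct array (-1.78 to -2.06), and that of Npl ended without oil oviduct replicate 1 (-1.51) or any E2 oviduct array (-1.51 to -1.59). In a fit of the oviduct arrays alone Acod1, Npl and St6gal2 lost theirs.

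**Figure D4:**
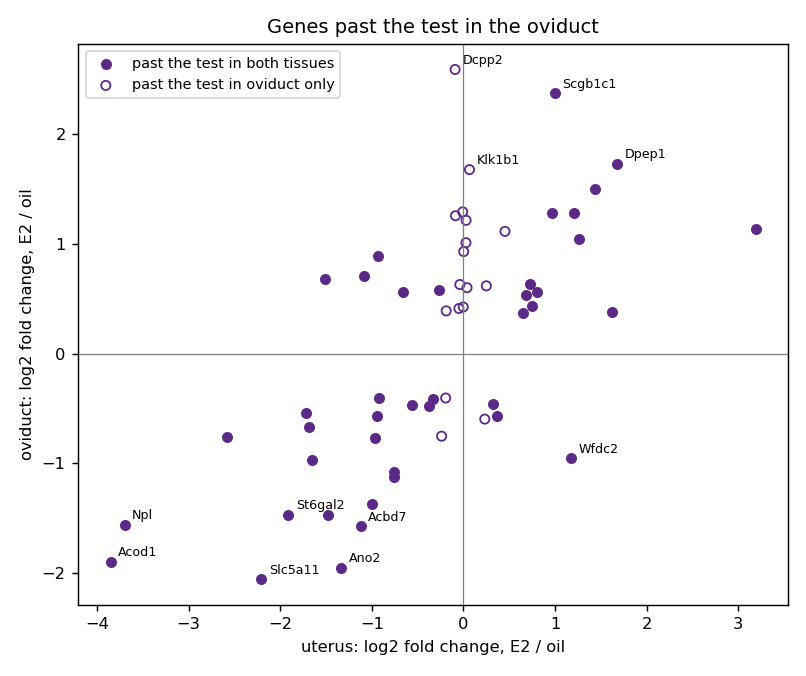
Log2 fold change of E2 over oil in uterus (horizontal) and oviduct (vertical) for the 58 genes past the test in oviduct. Filled points, which also passed it in uterus, include 33 that moved the same way in both tissues and 8 that moved in opposite directions.

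Wfdc2 went in opposite directions, rising by 1.18 in uterus (SE 0.12) and falling by 0.95 in oviduct (SE 0.12), and its interaction difference was -2.13 (SE 0.17, adjusted p = 2.1e-05). Its oviductal call ended without E2 oviduct replicate 1 (-0.91) or 2 (-0.95), and in a fit of the oviduct arrays alone. In all, 3 genes rose in uterus and fell in oviduct, and 5 did the reverse, close to the 3.23 and 4.58 expected of independent lists. Across all genes the E2 effects of the tissues correlated at Pearson r 0.299 (Spearman rho 0.284), over genes that are not independent and from mice that the tissues may share. The 33 genes of shared direction became 74 without both oil replicate 3 arrays, 8 to 10 without an E2 oviduct array, and 16 to 19 without any other array outside oil replicate 3.

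Between the tissues of oil mice, which checks the tissue labels, ciliated and epithelial genes were higher in oviduct and cell cycle and endothelial genes in uterus. With estimated correlations camera called 0 of the 38 lists here. By limma 3443 genes were higher and 4282 lower in oviduct (n = 3 arrays per group), 1008 and 550 by at least 2-fold. The protease inhibitor gene A2ml1 was higher by 7.29 log2 units (SE 0.15, adjusted p = 7.2e-11). Sntn, a protein of the ciliary tip (6.18, SE 0.23), the outer arm dynein Dnah12 (5.50, SE 0.21), the radial spoke protein Rsph4a (5.46, SE 0.18) and Fam216b (5.51, SE 0.21) followed. Lower in oviduct were Angptl7 (-4.72, SE 0.14), Spink1 (-4.29, SE 0.24), the glutamate receptor Gria4 (-4.11, SE 0.15) and the posterior patterning genes Hoxa11 (-3.92, SE 0.10) and Hoxd11 (-3.69, SE 0.13). For each of these 10 genes at least 1 of the tissue means lay below the highest Y-linked value, so the exact folds are uncertain. Reproductive tract patterning genes as a list went both ways, with 4 of 16 higher and 7 lower (adjusted over the list alone, 5 and 8; camera adjusted p = 0.18).

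Ciliated cell genes were higher in 28 of 29 members and lower in 0 by limma (median 2.67; adjusted over the list alone, 28; camera adjusted p = 3.0e-21), with adjusted p = 0.42 with an estimated correlation. They lay 0.80 higher in oil oviduct replicate 3, and their median was 2.48 without that array. Epithelial markers were higher in 13 of 14 (median 1.34; adjusted over the list alone, 13; camera adjusted p = 1.9e-10; adjusted p = 0.38 with an estimated correlation). Cell cycle genes were lower in all 27 (median -1.66; adjusted over the list alone, 27; camera adjusted p = 4.1e-14; adjusted p = 0.42 with an estimated correlation). Endothelial markers were lower in 11 of 12 (median -0.94; adjusted over the list alone, 11; camera adjusted p = 7.1e-07; adjusted p = 0.42 with an estimated correlation), natural killer cell markers in 8 of 9 (median -1.32; adjusted over the list alone, 9; camera adjusted p = 0.00096; adjusted p = 0.54 with an estimated correlation) and stromal markers in 9 of 12 (median -0.56; adjusted over the list alone, 9, and 1 higher; camera adjusted p = 0.00079; adjusted p = 0.54 with an estimated correlation). Natural killer cell markers lay at -1.25 in oil uterus replicate 3 relative to the other oil arrays of that tissue. Fat cell markers were higher in 6 of 7 (median 1.34; adjusted over the list alone, 6; camera adjusted p = 0.011; adjusted p = 0.62 with an estimated correlation), and adiponectin (Adipoq) differed by 2.48 (SE 0.53). Without both oil replicate 3 arrays 3476 genes were higher and 3845 lower. The oil arrays of the tissues did not overlap in 46.6% of genes, where chance gives 10%.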

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

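The tests of neighbouring genes, of the stromal share, of macrophage markers and of single genes beyond the epithelial markers were chosen only after the results were seen, as was leaving out both arrays of oil replicate 3. Single far arrays were not tested within the groups of 3.

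The first pattern is the place of oil replicate 3, whose uterus and oviduct arrays share 52 genes displaced alike. A candidate explanation is a set of inherited variants, if both arrays came from the same mouse. Among the 52 genes, 10 neighbouring pairs (at most 20 measured genes apart) occurred. Random sets matched on level had a mean of 2.60 and a highest count of 10. Some pairs belong to the same family, such as H2-Ab1 and H2-Aa, Ifit3 and Ifit1, or Trim12a and Trim30d. Such neighbours can be regulated together, which the random sets did not match, so the pairs cannot decide for inheritance. Of 17 interferon-stimulated genes, 17 lay lower in oil uterus replicate 3 and 16 in oil oviduct replicate 3. A different hormonal state stays open too, for part of the genes. The displaced genes were called for E2 in uterus at an odds ratio of 3.51 against other genes (57.7% against 28.0%, two-sided Fisher's exact p = 7.8e-06; level-matched random sets averaged 32.1%), but 22 of the 52 had moved the way E2 moves them, and 41 lay outside the range of all 10 other arrays, E2 arrays included, in both tissues. Neither explanation is excluded, and each may account for part of the genes; a shared handling batch was not tested, as the labels give none.

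The second pattern is the luteal genes of oil oviduct replicate 3. Akr1c18, Cyp11a1, Hsd3b1 and Star had a median displacement of 0.23 in the uterus array of that number against 3.93 in the oviduct array. The uterus array thus did not share the displacement. That cannot decide whether the whole mouse differed, since genes of the corpus luteum need not change in the uterus of such a mouse. Ovarian tissue carried over with the oviduct may be the source, since 11 further luteal genes had a median displacement of 0.156, above 99.4% of random lists matched on level, with Fdx1 at 0.84 and Scarb1 at 0.93 but Cyp17a1 at -0.55. Of these 11 genes 7 were higher, and no biological explanation from the design was tested. All 29 ciliated cell genes also lay higher in that oviduct array (median displacement 0.80). Whether carried-over tissue bears on the ciliated cell genes was not tested.

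The third pattern is the composition of the E2-treated uterus. A larger epithelial share of the RNA is argued against as the reason for the rise of macrophage markers, which it would dilute. Their mean rose by 0.72 (SE 0.09, and 0.65 without oil uterus replicate 3, which was lower). That rise does not bear on genes of the epithelium, whose markers ranged from -0.26 to 2.58. The genes Aoc1, Gabrp, Lcn2, Ltf and Prap1 rose past every epithelial marker (one-sided test, Holm-adjusted p at most 0.0054). They are among the largest rises, and their oil means lay below the highest Y-linked value, so this cannot decide the question for them. A smaller stromal share is argued against for the cell cycle genes. Their mean fell by 0.97 log2 units more than that of stromal markers (SE 0.23, difference -0.97). That holds only if E2 did not raise the stromal markers within cells, which was not tested. For raised genes other than the macrophage markers the share stays open, since the only bound tested was too lenient to decide. Of 2478 genes 1.29% rose beyond the highest marker, Elf3, against a median rise of 0.50, and the markers themselves may respond to E2.

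Tests of the difference between the tissues singled out 1150 genes with a more positive and 1138 with a more negative E2 effect in oviduct than in uterus. The named genes among them were Spink1 (3.87), Angptl7 (3.56), Lrp2 (3.46), Cxcl15 (3.17), Ndp (2.95), Il13ra2 (2.89), Lcn2 (-4.17), Gabrp (-5.13), Prap1 (-5.14), Ltf (-5.23), Aoc1 (-5.60) and Clca1 (-6.13). Gene lists whose median effect differed toward higher values in oviduct were progesterone-dependent genes (0.77), gland genes (0.70), cell cycle genes (1.14), endothelial markers (0.37), protein folding genes (0.66) and sterol synthesis genes (0.28). Lists that differed toward lower values were E2-induced genes (-1.50), oviduct secretory markers (-1.02), smooth muscle genes (-0.25), ion transport genes (-0.16), mucosal defence genes (-0.63), complement genes (-0.16), interferon-stimulated genes (-0.63), epithelial markers (-1.01) and cornified envelope genes (-0.088). With an estimated correlation 3 of these 15 lists held, those of progesterone-dependent genes, oviduct secretory markers and mucosal defence, and the adjusted p of the others ranged from 0.0576 to 0.878. These lists are not independent, since Lcn2 and Wfdc2 are listed in both the oviduct secretory and the mucosal defence lists. Sox17 is listed in both the oviduct secretory and the progesterone-dependent lists.

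Probe sets without a listed gene, which the comparisons of genes leave out, also responded. Of 12146, limma called 1045 in uterus (511 higher and 534 lower) and 2 in oviduct, both higher.

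The 3 against 3 arrays of a comparison can be split in 10 ways, too few for a share under 0.05. As many genes as the real split came from 1 of the 10 splits in uterus (5332 genes, highest of the other splits 0), 1 in oviduct (58, highest other 1) and 1 between the oil tissues (7725, highest other 1). For the interaction, 100 splits of the treatment labels were compared, the real one among them. Of these, 7 gave at least the real 2288 genes, the real split included, the highest 4277, so chance is not excluded by this count. All 7 were among the 9 splits, the real one included, that kept the uterine groups together. That points to the large uterine effect as the structure behind them. Splits that parted those groups gave at most 2 genes.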

How the results depend on the processing

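Leaving out both arrays of oil replicate 3 was the only alternative chosen after seeing the data. Of the counts of genes under an alternative, 161 stayed within 1.5 times the reported count and 60 did not; of results for single named genes, 6033 stayed on their side of the threshold, 285 lost and 54 gained a call, and 0 changed sign with a call on either side. Values short of the threshold did change sign, as Foxj1 in oviduct did without both oil replicate 3 arrays (0.24). Where a setting moved a result, the cause was not tested.

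A threshold of 2-fold, a stricter rule by construction, left 405 higher and 281 lower genes in uterus, 14 and 10 in oviduct, 234 and 334 for the interaction, 1008 and 550 between tissues, and 12 genes shared between the E2 effects. Array weights gave 4019 higher genes in uterus, 128 and 136 in oviduct, 2186 and 2345 for the interaction and 157 shared genes. The fit for each tissue alone, with fewer arrays behind the spread, gave 6 and 4 in oviduct and 6 shared. The Y-linked filter, with fewer genes tested, gave 51 higher in oviduct and 50 shared. Testing each probe set, with more tests, gave 10 and 9 in oviduct and 12 shared. Without both oil replicate 3 arrays there were 49 and 72 in oviduct and 74 shared. Leaving out each array in turn gave 7 to 36 higher and 7 to 36 lower genes in oviduct, 729 to 1228 more positive genes for the interaction, and 8 to 40 shared genes.

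The labels do not say that replicate numbers pair arrays, so pairing was not used. Of 12 arrays 5 correlated best with their own number in the other tissue, among them both arrays of oil replicate 3 and of E2 replicate 1. Residuals of the same number correlated between uterus and oviduct at 0.0045, 0.047 and 0.26 in oil mice and 0.26, 0.026 and 0.034 in E2 mice. Some arrays matched under other numbers, oil uterus 1 with oil oviduct 2 (0.26), oil uterus 2 with oil oviduct 1 (0.23) and E2 uterus 3 with E2 oviduct 2 (0.24). The best matches of E2 uterus 2 (0.029) and E2 oviduct 3 (0.034) were weak. Shared mice under other numbers therefore stay open and were not tested. With the number as a replicate block, 16 genes were lower in oviduct, without Acod1, and 21 were shared; the other gene counts stayed within 1.5 times.

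With estimated correlations camera called 0 lists higher and 0 lower in uterus, 0 and 0 in oviduct, 1 and 2 for the interaction, and 0 and 0 between tissues. Fry called 0 and 0 in oviduct and 11 lower between tissues. On genes above the 40th percentile 0 lists were lower in oviduct. Without both oil replicate 3 arrays 8 were higher and 3 lower there, and 3 to 7 and 1 to 3 with each array left out in turn. Cell cycle genes turned to a called rise of 0.13 in oviduct without both oil replicate 3 arrays, and ciliated cell genes to 0.096. Leaving out single arrays moved the ciliated list between -0.39 and 0.096 in oviduct and between -0.38 and 0.13 for the interaction, both highest without oil oviduct replicate 3. Steroid metabolism genes, with a median of 0.50 between tissues, took the opposite direction under fry to that of camera. The 10257 genes below the Y-linked level on all arrays limit what dim genes show.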

Other observations

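The gene families below were chosen after their values were seen, and so were the shares of genes with disjoint arrays; the correlation test of movement toward the oviduct was chosen before its result. In the uterus, 10 of 20 measured glutathione transferases, which detoxify reactive compounds, fell and 6 rose by limma (two-sided Fisher's exact test of lower genes against all other genes, adjusted p = 0.0040 over the families and tissues tested; the same test was used for the other families). Gsta4 fell by 1.03 log2 units (SE 0.11) and Gstm2 by 0.99 (SE 0.11), while Gstt2 rose by 1.53 (SE 0.10) and Gsto1 by 1.38 (SE 0.19). The counts were 10 and 6 under both other scalings, and near-identical copies make single members uncertain. Subunits of the vacuolar proton pump rose in 7 of 21 genes and fell in 0 by limma (adjusted p = 0.043 for higher genes; 7 and 6 rose under the other scalings), with Atp6v0d2 at 0.93 (SE 0.22) and Atp6v1a at 0.48 (SE 0.07).

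Mitochondrial ribosomal protein genes fell in 23 of 77 members and rose in 2 in uterus (adjusted p = 0.0052 for lower genes; 24 fell under both other scalings), with Mrps22 at -0.57 (SE 0.07) and Mrpl19 at -0.46 (SE 0.07). Proteasome genes fell in 15 of 50 members and rose in 4 (adjusted p = 0.030 for lower genes; 17 fell under both other scalings). Psmd14 fell by 0.50 (SE 0.08). The 4 that rose were Psmb9 (0.39), Psmb10 (0.34), Psmb8 (0.32) and Psme1 (0.28), subunits known to be induced by interferon. In oviduct, 0 members of these 4 families passed limma's test. The family tests were not matched on expression level. The genes they compare with include many of the 10257 below the Y-linked level on all arrays. A family of well-expressed genes could therefore pass these tests through its level alone.

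The E2-treated uterus may move toward levels of the oviduct. Across genes, the uterine E2 effect correlated with the oviduct minus uterus difference of oil mice at a lowest r of 0.330 and a highest of 0.373 over 3 rotations with disjoint oil uterus arrays, over genes that are not independent. With shared arrays r was 0.404 and the covariance 0.110, of which sharing added 0.0093. With disjoint arrays, genes raised by at least 2-fold in uterus were called higher in oviduct more often than all genes were, in each rotation. Genes lowered by as much were more often called lower in oviduct. In these calls a single held-out array stood for oil uterus and the other groups supplied the spread, so the shares are not given. How much of this movement reflects cell composition stays open.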
